A study of Mus musculus with 9 samples.

How the data were processed

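PolyA+ RNA was sequenced from mouse embryonic stem cells and from embryoid bodies made from them, aggregates in which stem cells differentiate into the germ layers. The cells were wild type or Hnrnpll knockout and were collected at day 0, day 4 and day 8. The 9 libraries form 6 groups: 1 wild-type library per day and 2 knockout libraries per day, from the knockout lines that the labels call G6 and H8. Per the labels, stem cells grew in medium with 15% fetal bovine serum and leukemia inhibitory factor, and bodies formed in hanging drops; the labels name no feeder cells.

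The submitters' processing notes name HISAT2 2.0.5 and StringTie 1.3.3b with the mm10 genome build; the role of each, the options, the annotation and the use of strand are not given. For each library the authors deposited whole-number read counts per gene, with no scaling between libraries, and TPM (length-scaled transcript abundance) per gene, which sum to between 999787 and 1000218 in each library. The deposited counts of genes with low values (up to 40) fall on multiples of 4 more often than the 25% that chance gives. The share was 43.4% and 42.6% in the day 0 knockout libraries of G6 and H8, and 30.5% to 33.1% in the other libraries. Thus 1 count is not 1 independent fragment. Each count table also holds 259 entries with no gene name, which were left out. All 49326 named identifiers matched GENCODE M21, from which coordinates (mm10) and gene types were taken. Where several identifiers share 1 symbol (132 identifiers), they were kept apart. The tables give values per gene and none per transcript or junction, so splicing was not examined.

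Total counts per library ran from 54218051 to 184952442. A gene at 0 counts in a group was given a floor of 3 counts over the group, and a fold against it is stated as a lower bound; such floors cover counting error only, since reads carry no molecular identifiers, and where counts come in steps of 4 the bounds would be up to 4 times lower. Of 212 genes named, 97 overlap another annotated gene; since the use of strand is not given, their counts, and those of close paralogs, are uncertain.

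Genes needed the CPM (counts scaled to library size) that equals 10 counts in the median library (0.079) in at least 2 libraries, which left 24794 genes. Counts were normalised by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Comparisons within a day, along the knockout course and between days (interactions) came from a model with a mean for each of the 6 groups. Its spread comes from the 2 knockout lines at each day (3 residual degrees of freedom; prior degrees of freedom 3.12, common biological coefficient of variation 0.348); the lone wild-type library of a day is assumed to vary like the knockout libraries. Knockout against wild type over all days came from an additive model of day and genotype (5 residual degrees of freedom; prior 3.49, coefficient 0.494). In total 8 comparisons were tested. The wild-type course has 1 library per day and is given as values without a test. Because wild type is a single line, genotype and line cannot be separated in any comparison.

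The groups, comparisons, 25 gene lists, 30 genes always reported and the rule for further names were fixed before the data were examined. The rule added, for each comparison, the 6 genes with the largest rise and the 6 with the largest fall among genes past the threshold with a mean of at least 5 CPM and 1 sign in both knockout lines (predicted and clone names left out), and up to 4 members of each list with members past the threshold. Any gene named outside it is said to be chosen after its values were seen. The lists were naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesendoderm, definitive endoderm, extraembryonic endoderm, cardiac mesoderm and cardiomyocyte, haemato-endothelial, neuroectoderm and neuron, trophoblast, 2-cell-like, germline, Hox clusters, fibroblast and mesenchyme, epithelial, splicing factors and hnRNPs, p53 targets, glycolysis and hypoxia, cholesterol synthesis, cell cycle, interferon-stimulated, imprinted, mitochondrially encoded, immediate early and stress, and sex-linked line identity. Members were counted by adjustment over all genes and by adjustment over the list alone. Lists with at least 5 tested members were tested with camera, at a preset correlation between genes of 0.01 and with an estimated correlation, and with fry, each adjusted over lists within a comparison.

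The alternatives were other normalizations, no filter, DESeq2 1.42.0, limma-voom, TPM with a pseudocount of 1 or 0.1, a replicate block, each line or library left out, and a log2 fold change over 1 as a further criterion. The replicate block takes the knockout line as a term (2 residual degrees of freedom), since the differences between the lines were correlated between days across 15732 genes (Pearson's r 0.196, 0.135 and 0.367; genes are not independent replicates). Over all days it was a random effect in limma-voom with 3 lines, with an estimated correlation of -0.193 within lines. Counts divided by 4, a filter at 1 CPM, counts thinned to the smallest library, a fit without the day 0 libraries and a fit of protein-coding genes were added after the data were seen.

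The tests were tested on simulated data for 24794 genes in 4 of the comparisons, with changes of 2-fold, 4-fold and 8-fold put into 67, 67 and 66 genes at 1 CPM or more and the others left unchanged. Over all days the additive model recovered 58.2% of genes changed 2-fold, 97% of those changed 4-fold and 100% of those changed 8-fold. The simulated counts had the spread of the model of group means (coefficient of variation 0.348) and no change of the genotype difference between days. In the data the additive model had a coefficient of 0.494, so its recovery there was not measured by these shares. The model of group means recovered 7.46%, 67.2% and 92.4% at day 8, and 5.97%, 17.9% and 68.2% for the interaction from day 0 to day 4. Between 1 and 7 unchanged genes were called per comparison, with the same limit for the additive model. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.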

Results

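The data are polyA+ RNA-seq profiles of mouse embryonic stem cells (day 0) and of the embryoid bodies that they formed after 4 and 8 days in hanging drops. Wild type contributed 1 library at each day, and the Hnrnpll knockout contributed 2 libraries at each day, from lines G6 and H8. Hnrnpll encodes an RNA-binding protein of the hnRNP family, known as a splicing regulator in lymphocytes and plasma cells, and the series asks how its depletion alters gene expression during embryoid body formation. Total counts were 113059196, 122111155 and 135562895 in the wild-type libraries of day 0, 4 and 8. The knockout libraries had 54218051 and 61626609 at day 0, 126467666 and 137745816 at day 4, and 154674240 and 184952442 at day 8 (line G6 first), so the day 0 knockout libraries were the shallowest. Between 15492 and 16499 genes reached 1 TPM per library. In a principal component analysis the first component (36.7% of variance) set the day 0 knockout libraries (-164.1 and -176.2) apart from the other libraries (-14.17 to 122). The second (20.1%) set the day 8 wild-type library (174.6) apart. The third (12%) set the day 0 wild-type library (-130.7) apart from the others (-37.31 to 59.04).

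Hnrnpll RNA remained present in both knockout lines. The gene (ENSMUSG00000024095, chromosome 17, 80029487 to 80062334, minus strand) was measured at 77.1, 101 and 112 TPM in wild type at day 0, 4 and 8. In the knockout it was measured at 39.7 ± 21.5 TPM at day 0, 49.9 ± 16 TPM at day 4 and 50.03 ± 9.19 TPM at day 8 (mean ± SD, n = 2 lines). The log2 differences from wild type were -0.996, -1.07 and -0.975, and none passed the test within a day (adjusted p = 0.245, 0.376 and 0.212). Over all days the log2 difference was -1.02 (adjusted p = 0.0726). With the replicate block the difference passed at day 8 (adjusted p = 0.0458). Over all days it passed in limma-voom (adjusted p = 0.0365), also with the line as a random effect (0.0109), whose negative correlation (-0.193) narrows the error. Its paralog Hnrnpl was measured at 321 to 389 TPM in wild type, and its log2 differences were 0.53, -0.14 and 0.19 (adjusted p = 0.122, 0.758 and 0.482). Values per gene do not show whether the remaining Hnrnpll RNA encodes protein.

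**Figure D1:**
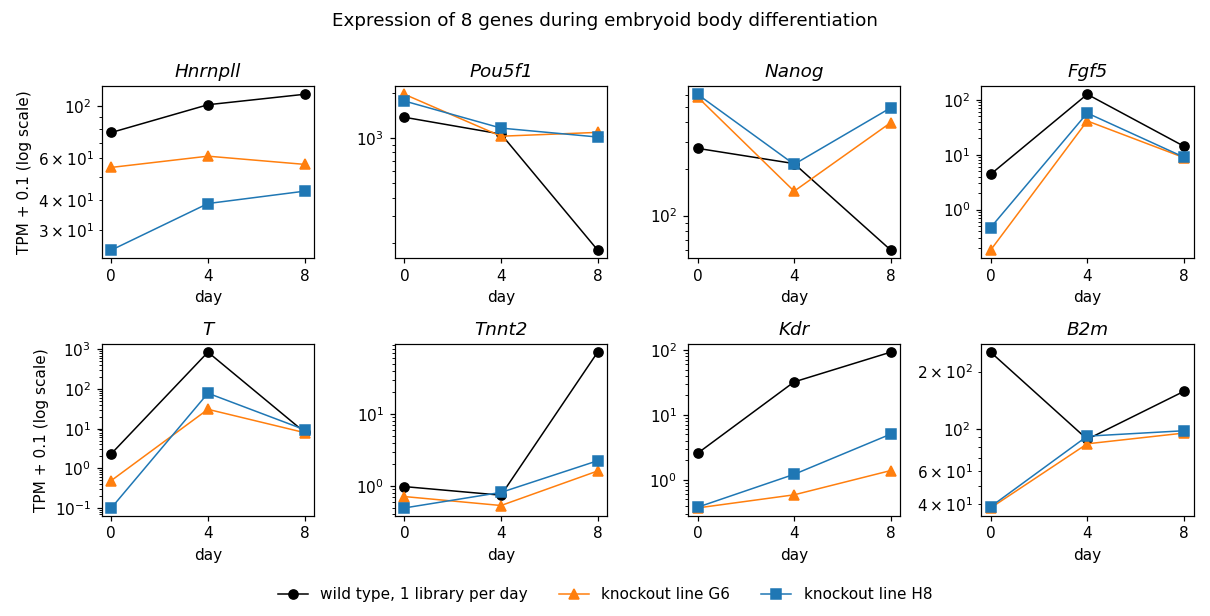
TPM + 0.1 on a log scale against day (0, 4 and 8) for 8 genes, with 1 point per library: wild type as black circles, knockout line G6 as orange triangles and line H8 as blue squares. At day 8 Pou5f1 was at 178 TPM in wild type and near 1050 TPM in the knockout lines, while Tnnt2 was at 72.5 TPM in wild type and near 1.82 TPM in the knockout lines.

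The wild-type course gives the background against which the knockout was compared, from 1 library per day and with no test. Its log2 differences are of TPM + 1, which shrinks them where TPM is low. They are therefore not on the scale of the edgeR values given for the knockout. From day 0 to day 4 the primitive streak genes T, Mixl1 and Eomes had log2 differences of 8.05, 7.42 and 5.6, and the epiblast gene Fgf5 had one of 4.58. The naive pluripotency genes Klf4, Zfp42 and Esrrb had differences of -3.7, -2.9 and -2.59, while Pou5f1, the central pluripotency factor, had -0.37. From day 4 to day 8 T had a difference of -6.56, Pou5f1 of -2.56 and Nanog of -1.84, while the naive genes Klf4, Tbx3, Zfp42 and Esrrb had 1.23, 1.23, 0.6 and -0.12. Over the same interval the cardiac troponin gene Tnnt2 had 5.48 (0.642 to 72.5 TPM) and the cardiac transcription factor gene Isl1 had 3.18. The yolk sac gene Afp had 4.37 (0.245 to 24.8 TPM). The embryonic globin gene Hbb-bh1 was at 0 TPM until day 4 and at 462 TPM at day 8.

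Over all days, the knockout libraries held higher levels of several naive pluripotency and glycolysis genes and lower levels of single genes of mesoderm, endoderm and trophoblast than the wild-type libraries of the same days. Fgf4, a growth factor made by pluripotent cells (chromosome 7, 144847367 to 144865243), was 4.35-fold higher (log2 2.12, SE 0.217, adjusted p = 0.0212). Kdr, the VEGF receptor of endothelial progenitors (chromosome 5, 75932827 to 75978458), had a log2 difference of -4.58 (SE 0.547, adjusted p = 0.0215), and the caudal gene Cdx2 had one of -3.64. The Y-linked genes Eif2s3y, Ddx3y and Uty were near or at 0 in both knockout lines at every day, against 82.2 to 134 TPM for Eif2s3y in wild type. Of 24794 genes tested, 244 differed, 96 higher and 148 lower in the knockout, each with 1 sign in both lines against wild type.

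In the naive pluripotency list 3 of 16 members rose over all days (Fgf4, Klf5 at 2.26 and Tfcp2l1 at 1.15) and 8 did when adjusted over the list alone; the list median was 1.1. Esrrb (1.84), Zfp42 (1.67), Nanog (1.05) and Pou5f1 (0.85) did not pass (adjusted p = 0.0519, 0.0519, 0.328 and 0.324). In the general pluripotency list none of 15 rose and Lin28a fell (-0.91), against 6 higher and 1 lower adjusted over the list alone. Among 27 tested genes of glycolysis and hypoxia, Pfkp (1.59), Gpi1 (1.04), Hk2 (1.04) and Aldoa (0.77) rose, and 6 did adjusted over the list alone. Hand1 (-2.47), a factor of heart and trophoblast, fell, as did the endoderm factor Foxa2 (-2.46), the N-cadherin gene Cdh2 (-3.22), the smooth muscle gene Tagln (-1.66), and the imprinted genes Peg3 (-2.24) and Magel2 (-1.93). Among 46 splicing factors and hnRNPs, Khdrbs1 (-0.9) and Ptbp2 (-0.98) fell, and 4 did adjusted over the list alone. Aplnr fell by 5.77 on the log2 scale. Hapln1, Lum, Nepn and Apoc2 passed with differences that rest on day 8: wild type was at 26.9, 56.8, 42.3 and 112 TPM at day 8 and at 0.557 TPM or less before, and the knockout was at 0 counts at days 0 and 4, so no fold over all days is given. Further rises were those of Ndufa4l2 (2.61), Aire (2.74), Laptm5 (2.74), Rgs22 (2.8), Crtac1 (2.53), Slc1a1 (2.66), the tight junction gene Tjp3 (1.42) and the stress-responsive growth factor Gdf15 (2.38). No member passed in the lists of primitive streak (median -1.81; 6 lower adjusted over the list alone), Hox clusters (-1.59; 0), interferon-stimulated genes (-1.13; 0), cholesterol synthesis (0.171; 0), cell cycle (0.108; 0) or mitochondrially encoded genes (0.0564; 0).

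The test was edgeR on the additive model, and 4877 genes had an unadjusted p under 0.05. The count rests on single libraries: without the wild-type library of day 0 or day 8 it was 467 or 42, without the day 0 library of G6 or H8 70 or 20, without either day 4 knockout library 0, and without the day 8 library of G6 or H8 59 or 2. All 34 named calls ended with either knockout line alone, which gave 0 genes (2047 and 2662 at an unadjusted p under 0.05), and without the day 0 libraries the count was 14. Other settings gave more: DESeq2 3348, limma-voom 885, and the mean of the per-day contrasts 3585. In limma-voom with the line as a random effect the count was 4389, but the estimated correlation within lines was negative (-0.193), which narrows the error of a contrast that rests on 1 wild-type line, so the calls it adds, apart from that of Hnrnpll above, are not named. The share of higher genes was 39.3%, and 49.5% when libraries were scaled by total count; higher genes were the majority with log2 TPM (63.2% and 65% with a pseudocount of 1 and 0.1), with the mean of the per-day contrasts (51.9%) and without the wild-type library of day 0 (56.5%), while the share was 26.1% without that of day 4, 27.1% without the day 8 library of G6 and 28.6% without the day 0 libraries.

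At day 0, before differentiation, 20 of 28 interferon-stimulated genes and 11 of 20 genes of the 2-cell-like state were lower in both knockout lines than in wild type. B2m, the light chain of MHC class I (chromosome 2, 122147686 to 122153083), was at 253 TPM in wild type and 38.5 ± 0.402 TPM in the knockout (SD, n = 2), a 6.54-fold fall (log2 -2.71, SE 0.179, adjusted p = 0.00436). Ifit1, an interferon-induced RNA-binding protein, was at 36.3 against 0.112 ± 0.0621 TPM, and the guanylate-binding protein gene Gbp2 at 62.9 against 0.308 ± 0.172 TPM. The primed epiblast gene Fgf5 had a log2 difference of -4.08 (SE 0.617), while the naive genes Fgf4 (1.77), Zfp42 (1.09) and Esrrb (1.02) rose. Of 24794 genes, 1347 differed, 274 higher and 1073 lower in the knockout.

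Of 28 interferon-stimulated genes 20 fell and none rose; 25 fell adjusted over the list alone, and the list median was -2.98 (-3.24 in G6 and -3.05 in H8). Besides B2m, Gbp2 and Ifit1, they included the RNA sensor gene Ifih1 (-8.44), while Mx2 had 0 counts in both knockout lines and was at least 1270-fold lower (a bound that, like the others against 0 counts, is up to 4 times too high where counts come in steps of 4). Usp18, a negative regulator of interferon signalling, fell by 9.83 on the log2 scale. Outside the list, the related genes Gbp2b (-8.54) and Trim30a (-8.98) fell, and Ifit3b was at least 1240-fold lower. Ifitm2, also outside the list and named here after its values were seen, lay the other way. It was at 869 and 803 TPM in G6 and H8, against 104 TPM in wild type. In the 2-cell-like list 11 of 20 fell, and 19 did adjusted over the list alone (median -3.57). These included 6 Zscan4 genes and Usp17le (-3.82), which belong to families of near-identical copies, so that the level of any 1 copy is uncertain. Gm8300 (-3.54), Zscan4f (-4.51) and Zscan4d (-4.78) were among them. In the formative and primed epiblast list Fgf5 and the DNA methyltransferase gene Dnmt3b (-1.5) fell and none rose of 14, against 3 lower and 1 higher adjusted over the list alone. Naive pluripotency had 3 of 16 higher and 6 adjusted over the list alone.

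Epithelial genes were lower in part: Cldn6 (-2.07), Krt18 (-3.35) and Esrp1 (-2.12) fell of 18, while 10 were lower and 3 higher adjusted over the list alone. Glycolysis genes Ndrg1 (1.56), Gpi1 (1.21) and Pgk1 (1.05) rose of 27, against 10 adjusted over the list alone. Among neural genes Nes (-1.98) and Map2 (-1.53) fell, Msi1 rose (2.16), and Dcx was at least 11.4-fold lower. Further falls were those of Wnt3 (-5.96), Lrp2 (-2.49), Tagln (-2.09), Magel2 (-2.88), Lin28a (-1.36) and Khdrbs1 (-0.996), while Actc1 was at least 133-fold and Hoxb1 at least 14.5-fold lower. Utf1 (0.85), Tead4 (1.43), Tm7sf2 (1.56), Crtac1 (3.71), Atp2a3 (3.65), Nxph4 (4.15), Nkx6-3 (4.21) and the 7SL RNA genes Rn7s1 (5.17) and Rn7s2 (4.46), near-identical copies without a polyA tail in the cell, rose. In the fibroblast list only Tagln of 22 passed (median -0.955), and 20 of the 22 genes reached 1 TPM in wild type at day 0. No gene passed over all genes or over the list alone among p53 targets (median -0.0348), the cell cycle (0.106), mitochondrially encoded genes (-0.117), immediate early and stress genes (0.616) or germline genes (-0.708). In the haemato-endothelial list none of 22 passed over all genes and 3 were lower adjusted over the list alone.

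At day 0 edgeR gave 6038 genes with an unadjusted p under 0.05, and 2.81 genes fell for each that rose in a fit of protein-coding genes, which called 434. Pseudogenes were 498 of the 1073 lower genes (46.4%) and 11.4% of the genes tested. Median processed pseudogene levels were 0.2 and 0.22 CPM (counts scaled to library size) in the day 0 knockout libraries against 0.456 to 0.648 in the other 7. The same 2 libraries were the shallowest and had the most low counts on multiples of 4 (43.4% and 42.6%, against 30.5% to 33.1%). A technical difference of these libraries cannot be separated from genotype at day 0. The same limit holds for the knockout step and the interaction from day 0 to day 4. The count was 376 or 374 without the day 4 library of G6 or H8, 591 or 565 without their day 8 library, and 3737 with DESeq2; 25 of the 48 named calls ended without either day 4 knockout library. With the replicate block Cdx2 (-3.2, adjusted p = 0.017), Nanog (1.14, 0.0397) and Kdr (-3.13, 0.0343) passed, while Tm7sf2 (0.0521) and Dcx (0.0632) did not.

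At day 4 the median of the primitive streak list lay below wild type in both knockout lines, but none of the 18 genes passed over all genes, and neither the fry test of the list (adjusted p = 0.0789) nor camera (adjusted p = 0.327 with an estimated correlation) passed. T, the brachyury gene of the streak (chromosome 17, 8434423 to 8442496), was at 853 TPM in wild type and 54.6 ± 33.8 TPM in the knockout (SD, n = 2). Mixl1 was at 256 against 5.25 ± 6.1 TPM and Eomes at 253 against 23.8 ± 5.3 TPM, with log2 differences of -5.65 and -3.47 (SE 1.28 and 0.459). The adjusted p values were 0.172 for T, 0.179 for Mixl1 and 0.115 for Eomes. The genes that passed were Eif2s3y, lower (-11.01, adjusted p = 0.0128), and Mir8114, higher (9.76, 0.048). Mir8114 had 1 count in the wild-type library, so that its fitted value is no bound, and it overlaps Glul, so that its level is uncertain. In wild type it was at 193 and 163 TPM at day 0 and day 8, against 152 and 120 TPM in G6 and H8 at day 4. Its call thus rests on the lone wild-type library of day 4.

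In the primitive streak list none of 18 passed over all genes, 13 were lower adjusted over the list alone, and the median was -3.71 (-3.78 in G6, -3.36 in H8). Glycolysis and hypoxia had a median of 1.01 with 0 of 27 past the test and 15 higher adjusted over the list alone. General pluripotency (median 0.845) had 7 higher and 1 lower adjusted over the list alone, naive pluripotency (0.715) had 6 higher, p53 targets (0.614) had 6 higher, and interferon-stimulated genes (-0.41) had 8 lower and 1 higher. Pou5f1 was at 1060 TPM in wild type and 1093 ± 96.3 in the knockout. Esrrb (1.68), Zfp42 (1.29) and Sox2 (1.25) did not pass (adjusted p = 0.0788, 0.121 and 0.126), nor did Kdr (-5.4, adjusted p = 0.128). The neural gene Sox1 was at 0 counts in wild type and at least 33.8-fold higher in the knockout, without passing (adjusted p = 0.128). For the cardiac list the median (0.172) was positive and the camera test pointed down, and the same held for the Hox list (0.0905).

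For day 4 edgeR gave 3352 genes with an unadjusted p under 0.05, against 2 called; DESeq2 called 1320, limma-voom 56, and log2 TPM 55 or 10 with a pseudocount of 1 or 0.1. The count was 1 with the replicate block, where Mir8114 no longer passed (adjusted p = 0.0561), and 1 with total count scaling. It was 0 without either day 0 knockout library, 1 or 0 without the day 4 library of G6 or H8, 1 without either day 8 knockout library, and 6 without the wild-type library of day 8.

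At day 8, 11 of 16 naive and 12 of 15 general pluripotency genes were higher in the knockout, while 13 of 24 cardiac genes, 8 of 22 haemato-endothelial genes and 13 of 28 imprinted genes were lower. Pou5f1 (chromosome 17, 35506018 to 35510772) was at 178 TPM in wild type and 1050 ± 52.9 TPM in the knockout (SD, n = 2), 6.4-fold higher (log2 2.68, SE 0.191, adjusted p = 0.0142). Nanog was at 59.8 against 447 ± 69.4 TPM and Esrrb at 20.9 against 224 ± 6.48 TPM. Tnnt2, the cardiac troponin T gene (chromosome 1, 135836354 to 135852260), was at 72.5 against 1.82 ± 0.443 TPM, a 35.2-fold fall (log2 -5.14, SE 0.486, adjusted p = 0.0142). Of 24794 genes, 2446 differed, 1241 higher and 1205 lower in the knockout.

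In the naive pluripotency list 11 of 16 rose and none fell (14 adjusted over the list alone), with a median of 2.54; they included Nanog (3.02), Esrrb (3.11), Zfp42 (2.87) and Fgf4 (2.68). In the general pluripotency list 12 of 15 rose (12 adjusted over the list alone), among them Sox2 (2.46), Utf1 (2.89) and Gdf3 (2.6), and Lin28a, named after its values were seen, fell (-0.78). Germline genes followed with 6 of 19 higher (14 adjusted over the list alone; median 2.12), among them Tex19.1 (2.67), Tdrd12 (2.27), Piwil2 (2.64) and Rpl10l (3.24). Foxd3 (2.8) rose in the epiblast list, Sp110 (3.64) and Gm8300 (2.1) in the 2-cell-like list (8 adjusted over the list alone), and Stmn2 (2.7) in the neural list. Interferon-stimulated genes, lower at day 0, were in part higher at day 8: 6 of 28 rose, among them Oas2 (2.92), Irf1 (1.59), Oas1a (2.36) and Ifitm3 (1.78), with 9 higher and 2 lower adjusted over the list alone. Apart from the lists, Halr1, a non-coding RNA gene of the HoxA region, rose (6.85), as did Spata31d1b (5.43), Trim52 (5.14) and Cyct (5.09). Klhdc7a had 0 counts in wild type and was at least 947-fold higher.

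In the cardiac list 13 of 24 fell and none rose (22 adjusted over the list alone; median -3.42), including the sarcomere genes Actc1 (-6.75), Myh7 (-5.38), Myh6 (-3.77) and Ttn (-3.08) and the progenitor factor Isl1 (-3.57). In the haemato-endothelial list 8 of 22 fell (17 lower and 2 higher adjusted over the list alone; median -3.03), among them Kdr (-4.81), Lmo2 (-3.44), Esam (-3.1) and Cd34 (-2.96). The fibroblast and mesenchyme list had 10 of 22 lower (19 adjusted over the list alone; median -3.33), with Col3a1 at -6.85, Pdgfrb at -3.65, Col5a2 at -3.54, Mmp2 at -2.12 and Tagln at -2.04. Hox genes, which pattern the trunk, had 10 of 38 lower (21 lower and 1 higher adjusted over the list alone; median -3.27), among them Hoxb8 (-4), Hoxd13 (-3.4), Hoxd8 (-2.99) and Hoxb9 (-2.95). Imprinted genes, many of them regulators of fetal growth, had 13 of 28 lower (17 lower and 1 higher adjusted over the list alone; median -2.07), including H19 (-6.64), Mest (-4.14), Igf2r (-2.83) and Gnas (-2.03). Yolk sac and endoderm genes Rbp4 (-4.37), Apoc2 (-4.66), Ttr (-3.96) and Apob (-3.54) fell in the extraembryonic endoderm list (4 of 30; 8 adjusted over the list alone), and Foxa1 (-4.32) and Nepn (-7.17) in the definitive endoderm list (2 of 14; 6 lower and 1 higher adjusted over the list alone).

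Other lists had fewer members past the test. Among 46 splicing factors and hnRNPs 4 fell and none rose, Khdrbs1 (-0.97), Ptbp2 (-1.21), Mbnl1 (-1.46) and Hnrnpr (-0.67), and the same number fell adjusted over the list alone (median -0.242). The p53 targets Gdf15 (3.05) and Gtse1 (1.6) rose, and the replication genes Mcm5 (0.84), Mcm7 (0.7) and Ccne1 (1.28) rose while Ccne2 fell (-1.19). Of glycolysis and hypoxia genes 3 rose, including Pdk1 (1.47) and Gapdh (0.81), and Vegfa (-1.32) and P4ha1 (-1.54) fell. Nes (-1.66), Cdx2 (-3.41), Cyp51 (-1.01) and Fosb (-3.31) fell, and Hspa1b (1.7) and Xist (2.65) rose. The Y-linked genes Eif2s3y, Ddx3y and Uty had 0 counts in the knockout and were at least 14000-fold, 7990-fold and 5570-fold lower. Other Y-linked genes are named here after their values were seen. At day 8 Uba1y and Gm29650 were at 0 TPM in both knockout lines, and Mid1-ps1 and Gm4017 were below 1 TPM. Gm20775 was at 17.5 and 14.9 TPM in G6 and H8, against 12.6 TPM in wild type. Gapdh-ps15 was at 20.8 and 19.7 against 10.5 TPM, and Gm47283 at 63.6 and 36.3 against 67.2 TPM. No member passed over all genes in the streak list (median -0.0334; 0 adjusted over the list alone), the epithelial list (0.137; 5 higher and 1 lower) or the mitochondrially encoded list (-0.101; 0).

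At day 8 edgeR gave 7354 genes with an unadjusted p under 0.05, and the replicate block called 3091. Under it Hnrnpll, Foxa2 (-2.75, adjusted p = 0.0487), Hbb-bh1 (0.0171), Sox1 (2.45, 0.0449), Klf4 (1.91, 0.0482) and Gata6 (-2.65, 0.0462) passed as well, and Xist did not (0.0539). All 78 named calls ended without either day 4 knockout library, where the count was 0; it was 2 or 562 without the day 8 library of G6 or H8, with 76 or 36 named calls ended. Without the day 0 library of G6 or H8 it was 4216 or 4249, and without all day 0 libraries 4265; DESeq2 called 5455 and limma-voom 3769. The libraries of day 0 and day 4 do not enter the day 8 difference and act on these counts mainly through the shared spread. The median of all genes was 0.08 with TMM and -0.07 or -0.08 with log2 TPM and a pseudocount of 1 or 0.1. The higher genes made up 50.7%, against 59.2% with total count scaling, 35.2% with limma-voom and 38.9% with log2 TPM and a pseudocount of 1.

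**Figure D2:**
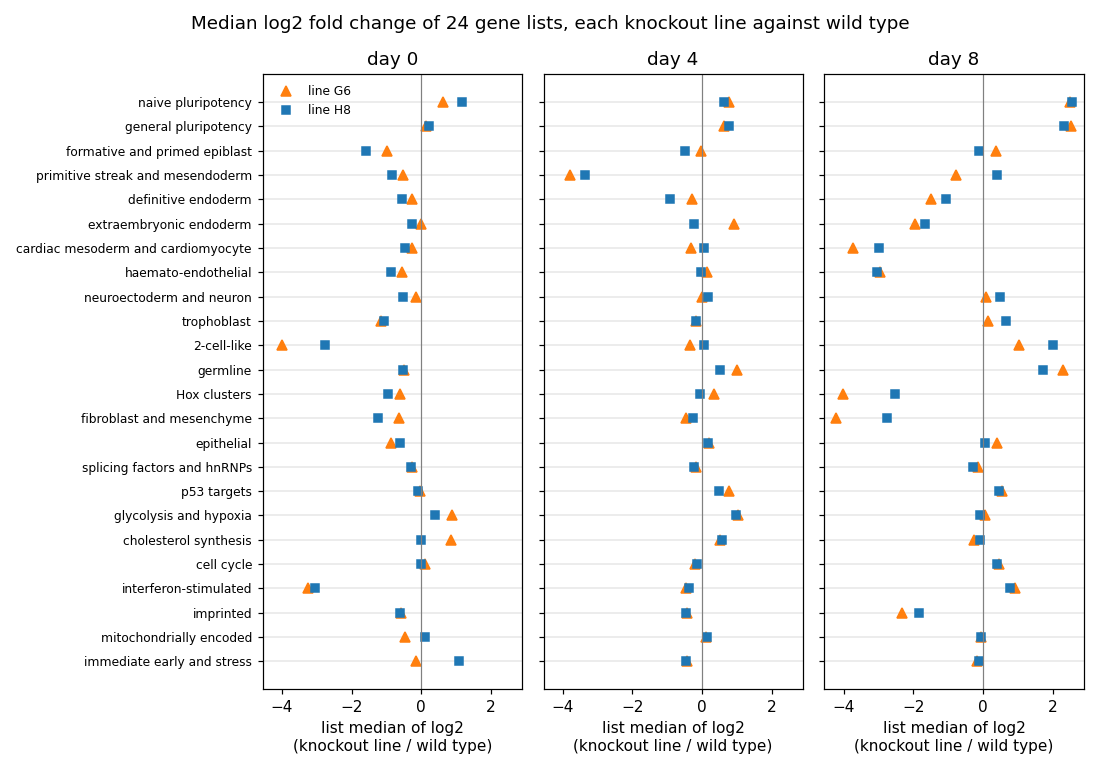
Median log2 fold change of 24 gene lists in each knockout line against the wild-type library of the same day (line G6 as orange triangles, line H8 as blue squares; panels for day 0, day 4 and day 8). The interferon-stimulated list lies at -3.24 and -3.05 at day 0, the primitive streak list at -3.78 and -3.36 at day 4, and the cardiac list at -3.72 and -2.98 at day 8.

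Along the knockout course from day 0 to day 4, 14 of 16 naive pluripotency genes fell, and 7 of 14 epiblast genes and 5 of 18 streak genes rose. Zfp42 (-2.64), Klf4 (-4.73), Tbx3 (-2.93) and Esrrb (-2.29, SE 0.133, adjusted p = 0.00138) fell, with 14 of 16 naive pluripotency genes lower (15 adjusted over the list alone; median -2.13). Fgf5 (7.55, SE 0.632), Dnmt3b (2.15), Sox3 (3.35) and Sall2 (4.12) rose, with 7 of 14 formative and primed epiblast genes higher and Foxd3, named after its values were seen, lower (10 and 1 adjusted over the list alone). In the streak list T (7.91), Wnt3 (8.29), Fgf8 (5.93) and Eomes (2.34) were among 5 of 18 that rose (8 adjusted over the list alone). Of 24794 genes 3650 changed, 2370 up and 1280 down.

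Pou5f1 (-0.77), Sox2 (-0.67), Gdf3 (-1.25) and Mybl2 (-1.37) fell among 8 of 15 general pluripotency genes, and Lin28a rose (1.15). Epithelial genes rose in 7 of 18 (12 adjusted over the list alone), including Cldn6 (3.28), Krt19 (2.59), Cldn7 (2.28) and Esrp1 (2.77). Interferon-stimulated genes rose in 12 of 28 and fell in 2 (12 and 3 adjusted over the list alone), with Gbp3 at 4.95, Gbp2 at 6.06, Ifih1 at 4.57 and Irf1 at 2.54. In the fibroblast list Col1a2 (-5.97), Col3a1 (-6.47), Prrx1 (-5.23) and Col5a2 (-2.88) were among 5 of 22 that fell (8 adjusted over the list alone); Col6a3 (-6.02), Col8a1 (-6.86), S100a4 (-6.06), Inhbb (-7.33) and Thbd (-6.05) fell as well. The vascular factor Etv2 (5.87) and Flt1 (3.58) rose and Pecam1 (-2.2) fell. Actc1 was at least 87.2-fold, Dcx at least 44.1-fold, Ttr at least 33.2-fold, Hoxd4 at least 25.1-fold and Hoxb1 at least 21.9-fold higher at day 4, and Magel2 (5.77), Peg3 (1.91), Fndc3c1 (8.54), Gadl1 (6.77), Lrp2 (2.94), Apob (3.56), Nes (2.75) and Foxa2 (3.26) rose. The immediate early genes Fosb (-4.74) and Fos (-3.13) fell and Ier3 rose (1.73), mt-Nd3 fell (-1.46), and 4 cell cycle genes, with Ccnb1 at -0.79, fell.

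For this step edgeR gave 7998 genes with an unadjusted p under 0.05; a fit of protein-coding genes called 2061 and DESeq2 called 6065. Of the 2370 genes that rose, 807 (34.1%) were pseudogenes. Without the day 4 library of G6 or H8 the count was 748 or 703, with 57 or 56 of the 93 named calls ended, and without the day 8 library of G6 or H8 it was 2232 or 2221. With the replicate block Cdx2 (2.82, adjusted p = 0.0107) passed, while Myh6 (0.0593), Ccne1 (0.0559), Tex19.1 (0.0559), Hoxc8 (0.0611) and Gcm1 (0.059) did not.

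From day 4 to day 8 of the knockout 2 of 16 naive pluripotency genes rose and 5 of 27 glycolysis and hypoxia genes fell. Zfp42 rose from 125 ± 2.18 to 497 ± 19 TPM (SD, n = 2; log2 2.004, SE 0.148, adjusted p = 0.0295) and Esrrb by 1.56, while Nanog (1.32) and Tbx3 (2.37) did not pass (adjusted p = 0.0939 and 0.0651). Over the same interval the wild-type values, with no test and as log2 of TPM + 1, were 0.6 for Zfp42, 1.23 for Tbx3 and -0.12 for Esrrb. In the naive list 2 of 16 rose, and 14 did adjusted over the list alone (median 1.9). In the glycolysis and hypoxia list 5 of 27 fell, among them Pgk1 (-1.77), Adm (-4.14), Bnip3 (-2.28) and Ndrg1 (-1.55), and 24 fell adjusted over the list alone (median -1.16). The trophoblast genes Rhox6 (3.51), Rhox9 (2.67) and Tead4 (1.66) rose of 16, and 11 rose and 1 fell adjusted over the list alone.

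Among other genes Anxa1 (4.39), Capn6 (4.33), Xaf1 (3.43), Cryab (3.24) and Serpinb9b (2.87) rose, and Apoc2, at 0 counts at day 4, was at least 125-fold higher. Ndufa4l2 (-4.04), Wnt8a (-3.39), Cnn1 (-3.18), Gbe1 (-2.98) and Ppp4r4 (-2.96) fell, as did Ier3 (-2.09), Nes (-2.35) and Cyp51 (-1.63), the last in a cholesterol synthesis list with 1 of 24 lower (6 adjusted over the list alone; median -0.992). The cardiac genes did not pass: Tnnt2 had a difference of 1.34 (adjusted p = 0.24) and none of 24 list members changed over all genes (5 higher and 1 lower adjusted over the list alone). Hbb-bh1 was at 0 counts at day 4 in both lines and did not pass (adjusted p = 0.454); at day 8 it was at 0 TPM in G6 and 2.61 TPM in H8, so no fold is given. In all, 77 genes changed, 41 up and 36 down.

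For day 8 against day 4, edgeR gave 3283 genes with an unadjusted p under 0.05; DESeq2 called 1565, limma-voom 408, a fit without the day 0 libraries 184, and the replicate block 150. Under the block Afp (6.54, adjusted p = 0.0401), Tbx3 (0.0459) and Nanog (0.0491) passed and Apoc2 did not (0.0551). Without the day 0 library of G6 or H8 the count was 164 or 172. It was 1 or 0 without their day 4 library and 2 or 0 without their day 8 library, where at least 22 of the 23 named calls ended.

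The interactions ask whether the gap between knockout and wild type differed between days. From day 0 to day 4 the difference changed for interferon-stimulated genes: 8 of 28 members passed and these moved up in the knockout relative to wild type, 21 did adjusted over the list alone, and the list median was 3.06 (fry adjusted p = 0.00708; camera adjusted p = 0.141 with an estimated correlation). At day 4 the list median remained below 0 (-0.41), while Oas2 was at 0.131 TPM in wild type and 1.46 ± 0.26 TPM in the knockout (SD, n = 2). B2m had a log2 change of the gap of 2.62 (SE 0.267) and Oas2 one of 4.99. In all, 125 genes passed, 113 up and 12 down. Eif2s3y (-4.13), Ifitm2 (-2.88), Mgat5b (-2.91), Plagl2 (-2.53), Cabp1 (-2.49) and Sall3 (-2.43) moved down, and Tgtp1 (6.28), Ddx60 (7.04), Tek (3.61) and Ier3 (2.85) moved up. Eif2s3y was near 0 in the knockout at both days, with 55 and 51 counts at day 0 and 7 and 4 at day 4. Of the 113, 69 (61.1%) were pseudogenes.

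For the step from day 0 to day 4, edgeR gave 4267 genes with an unadjusted p under 0.05, DESeq2 called 1898, limma-voom 0 (4284 at an unadjusted p under 0.05), log2 TPM 490 or 446 with a pseudocount of 1 or 0.1, and a fit of protein-coding genes 1. With the replicate block 12 genes passed; B2m (adjusted p = 0.0553), Oas2 (0.0542) and 13 more of the 18 genes that the naming rule took did not, while Mir8114, Kctd12 and Ddx60 did. The count was 200 or 81 without the day 0 library of G6 or H8, 1 or 0 without their day 4 library, and 0 without either day 8 knockout library.

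From day 4 to day 8 edgeR called 0 genes for the interaction, with 4041 at an unadjusted p under 0.05; DESeq2 called 1577, limma-voom 0 (4440 at an unadjusted p under 0.05), and the replicate block 0 (4495). The smallest adjusted p was 0.111, for Pou5f1 among others, whose gap changed by 2.71 (SE 0.24). Nanog (3.37), Tnnt2 (-5.3) and Nkx2-5 (-6.7) had adjusted p values of 0.114, 0.119 and 0.131. Adjusted over the list alone, 12 of 15 general pluripotency genes, 13 of 28 interferon-stimulated genes and 6 of 16 naive pluripotency genes moved up, and 17 of 24 cardiac genes moved down. Log2 TPM called 88 or 1 with a pseudocount of 1 or 0.1, and without the day 4 library of G6 edgeR called 1.

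Among the list tests, camera at the preset correlation passed the threshold for many lists in each comparison, for example for interferon-stimulated genes at day 0 (adjusted p = 3.66e-18), primitive streak at day 4 (8.13e-12), cardiac genes at day 8 (7.4e-12) and naive pluripotency at day 8 (3.62e-10). None of the camera calls held with an estimated correlation, where the smallest adjusted p over 25 lists and 8 comparisons was 0.0921 (interferon-stimulated genes at day 0). With an estimated correlation the adjusted p was 0.327 for primitive streak at day 4, and 0.167 at day 8 for the naive, general pluripotency, cardiac, haemato-endothelial and imprinted lists. For Hox, fibroblast and germline genes at day 8 it was 0.382. The fry test, which asks whether the genes of a list move 1 way, passed for interferon-stimulated genes at day 0 (adjusted p = 0.000795), and at day 8 for general pluripotency (0.00282), naive pluripotency (0.00869), cardiac (0.0123), imprinted (0.0155), interferon-stimulated (0.0155), haemato-endothelial (0.0179), definitive endoderm (0.0189) and germline genes (0.0418). It did not pass for the streak list at day 4 (0.0789) or for Hox and fibroblast genes at day 8 (0.0695). Along the knockout course it passed from day 0 to day 4 for naive pluripotency (0.00738), formative epiblast (0.00641) and epithelial genes (0.014), and from day 4 to day 8 for naive pluripotency and glycolysis (0.0227) and trophoblast (0.0464). For general pluripotency from day 4 to day 8 of the knockout, the camera call at the preset correlation (adjusted p = 0.0409) was lost with the replicate block (0.072). The median and the camera direction differed in sign for neural, epithelial and mitochondrially encoded genes over all days, for cholesterol synthesis in the knockout from day 0 to day 4, for definitive endoderm, cholesterol synthesis, imprinted and sex-linked genes in the interaction from day 0 to day 4, and for splicing factors and p53 targets in that from day 4 to day 8.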

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

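Among the tests below, those on depth, pseudogenes, feeder fibroblasts, undifferentiated cells and differences between lines were chosen only after the result was seen.

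The difference between knockout and wild type was itself tested for a change between days, and 125 genes passed from day 0 to day 4. The replicate block called 12 and ended 15 of the 18 calls that the naming rule took (B2m adjusted p = 0.0553, Oas2 0.0542), and a fit of protein-coding genes called 1. The calls of these 18 also ended without any 1 of the day 4 or day 8 knockout libraries, and 15 ended without the day 0 library of H8. The log2 change of the difference was 2.62 for B2m, 4.99 for Oas2, 6.28 for Tgtp1, 7.04 for Ddx60, 3.61 for Tek and 2.85 for Ier3. It was -2.88 for Ifitm2, -2.49 for Cabp1, -2.53 for Plagl2, -2.91 for Mgat5b, -2.43 for Sall3 and -4.13 for Eif2s3y. The value of Eif2s3y rests on few knockout counts, 55 and 51 in G6 and H8 at day 0 and 7 and 4 at day 4. Wild type had 12131 and 10333 counts at these days, so the gene was near 0 in the knockout at both. For Mx2 (11.67), Actc1 (10.04), Kctd12 (14.41) and Klhdc7a (9.38) at least 1 group is at 0 counts, and for Mir8114 (11.17) the wild-type library of day 4 has 1 count, so that these fitted values are no bounds. Kctd12 had 1812, 0 and 2999 counts in wild type at day 0, 4 and 8, and Mir8114 had 1273, 1 and 1174. The values of these genes rest on the lone wild-type library of day 4. By the fry test, the interferon-stimulated list changed from day 0 to day 4 (median 3.06, adjusted p = 0.00708) and from day 4 to day 8 (median 1.9, adjusted p = 0.0175), and the general pluripotency list from day 4 to day 8 (median 1.44, adjusted p = 0.0175). With an estimated correlation the camera adjusted p of these was 0.141, 0.257 and 0.257.

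Over all days 244 genes differed between knockout and wild type. Of 81 splits of the 9 libraries into 3 and 6, 1 gave as many genes, the real one, the highest other count was 4, and 77 splits gave 0. This cannot decide on chance, because libraries of 1 line are not independent. Each other split also puts wild-type and knockout libraries in the same group. Only 3 splits keep the lines whole, so the share cannot fall below 0.05 for lines. The Y chromosome, which covers 5 of the 244 genes, passed the limit of 0.3 for a copy difference at all 3 days. Its smallest median in G6 was -3.056, at day 0, from 6 genes and with an interval of -6.336 to 1.004. Of these genes 33.3% had a positive difference relative to all genes. Eif2s3y, Ddx3y and Uty were at 1.67%, 1.12% and 1.18% of wild-type TPM in G6 at day 0, and at 0 TPM at day 8. The largest autosome median held at all 3 days was 0.298 (chromosome 15 in H8, interval 0.252 to 0.344). By the condition written before, all autosomes below 0.3 at 1 or more days, an autosome copy difference would be excluded. It is left open because the interval reaches past 0.3, which was not part of that condition. In the knockout lines X-linked genes lay at -0.408 or lower relative to all genes at day 0, which argues against 2 active X chromosomes. Since wild type is 1 line, an effect of the knockout and a difference between lines cannot be told apart for the 244 genes.

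At day 0 the lower genes outnumbered the higher ones in the knockout, 1073 against 274 with edgeR, 2259 against 1478 with DESeq2, 342 against 34 or 339 against 35 without the day 4 library of G6 or H8, and 539 against 52 or 511 against 54 without their day 8 library. With the counts of all libraries thinned to the smallest total, 3.81 genes were lower per gene higher, so the total of counts alone is argued against. Thinning acts on finished counts, and 1 count is not 1 independent fragment. The test therefore cannot decide on the depth in fragments, which stays open. Pseudogenes were enriched 4.07 times among the lower genes, as a different placement of their reads would give, but as the whole cause this is argued against by a fit of protein-coding genes, with 2.81 lower per gene higher. For the interferon-stimulated list, fewer feeder fibroblasts in the knockout libraries are argued against: the list lay 1.82 or more below the fibroblast list in both lines (a difference of -1.82 in the nearer line), while 20 of 22 fibroblast genes reached 1 TPM in wild type and 18 in both knockout libraries, with Col1a2 at 72.4, Col3a1 at 11.6 and Tagln at 235 TPM in wild type and at 37.5 ± 19, 6.72 ± 3.54 and 55.7 ± 11.3 TPM in the knockout (SD, n = 2). An effect of the knockout on interferon-stimulated genes and a difference between lines remain open, as 1 wild-type line cannot separate them. A technical difference of the day 0 knockout libraries also stays open, since both libraries of that group share the low pseudogene levels.

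At day 8 pluripotency genes were higher and cardiac genes lower in the knockout. A mixture of undifferentiated cells with bodies otherwise like wild type would need a median share of 92.9% in G6 (25.5% to 100% by gene) and 56% in H8 (46.5% to 100%), from 11 general pluripotency genes, and at the medians would give cardiac medians of -3.28 and -1.13, against -3.7 and -3.09 measured on the same scale (log2 of TPM + 0.1). The fall went beyond the share by 0.42 in G6 (a difference of -0.42) and by 1.96 in H8 (-1.96), and exclusion had been set at more than 1 in both lines, so the mixture stays open. That limit can be read in more than 1 way, and the reading as a difference of medians was kept when its outcome was seen, since it excludes less. The lines differed by 0.17 in the general pluripotency median, which does not decide whether lines differ in this way whatever their genotype, because wild type is 1 line.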

How the results depend on the processing

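The alternatives that divide counts by 4, filter at 1 CPM, thin the counts, leave out the day 0 libraries or use protein-coding genes alone were chosen after the data were seen. For single genes, 3052 values without 1 library and 6006 under other settings kept their direction and their side of the threshold, 979 and 265 lost the call, 26 and 190 gained it, and 53 and 53 changed sign with neither value past the threshold; for lists, 769 and 447 kept both and 44 and 110 lost the call. Where a wild-type library is the only one of its day, leaving it out leaves no contrast for that day and no value. In the model of group means, a knockout library of a day outside a comparison acts on it mainly through the shared spread. Thinning all libraries to the smallest total gave 1283 genes at day 0 against 1347.

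Counts over 1.5 times away from the reported one were as follows; the cause was not tested, except that fewer samples or fewer genes enter where libraries, lines or gene types are left out. Over all days (244): no filter 382, DESeq2 3348, limma-voom 885, TPM 522 (pseudocount 1) and 632 (0.1), mean of per-day contrasts 3585, line G6 only 0 and H8 only 0 (2047 and 2662 with edgeR at an unadjusted p under 0.05), counts divided by 4 457, filter at 1 CPM 564, without day 0 libraries 14, protein-coding genes 509, replicate block as a random effect 4389. Day 0 (1347): DESeq2 3737, protein-coding genes 434. Day 4 (2): total count scaling 1, no filter 6, DESeq2 1320, limma-voom 56, TPM 55 and 10, replicate block 1, counts divided by 4 10, filter at 1 CPM 7, thinned 7, without day 0 libraries 0, protein-coding genes 4. Day 8 (2446): DESeq2 5455, limma-voom 3769, without day 0 libraries 4265. Knockout day 4 against day 0 (3650): DESeq2 6065, protein-coding genes 2061. Knockout day 8 against day 4 (77): DESeq2 1565, limma-voom 408, TPM with a pseudocount of 1 218, replicate block 150, counts divided by 4 239, filter at 1 CPM 188, without day 0 libraries 184, protein-coding genes 138. Interaction from day 0 to 4 (125): DESeq2 1898, limma-voom 0, TPM 490 and 446, replicate block 12, counts divided by 4 201, filter at 1 CPM 228, protein-coding genes 1. Interaction from day 4 to 8 (0; 4041 at an unadjusted p under 0.05): DESeq2 1577, TPM 88 and 1, counts divided by 4 1, thinned 1.

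Leaving out 1 library gave 0 to 467 genes over all days, 374 to 1625 at day 0, 0 to 6 at day 4, 0 to 4249 at day 8, 703 to 4049 and 0 to 172 along the knockout course, and 0 to 200 and 0 to 1 for the interactions. The median of all genes for the interaction from day 4 to 8 was 0.01 with TMM and -0.155 or -0.173 with TPM. Signs turned for Klhdc7a in the interaction from day 0 to 4 (-0.66 with TPM and a pseudocount of 1). Over all days they turned for the extraembryonic endoderm (0.287) and germline (-0.00417) medians without the wild-type library of day 8, and for the interferon-stimulated median without that of day 0 (0.115) or without all day 0 libraries (0.121). Leaving out 1 library at a time, these medians ran from -0.972 to 0.287, from -0.00417 to 1.26 and from -1.79 to 0.115. At day 0 the cholesterol synthesis median turned without the day 0 library of G6 (-0.0164) and was 0.823 without that of H8.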

Other observations

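The tests on chromosome 15 and chromosome 4 below were chosen only after the result was seen.

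The 2 knockout lines differed from each other along chromosome 15. Over 579 genes the median log2 difference of H8 from G6 was 0.36, and 90.2% of the genes were higher in H8; against wild type the medians were 0.38 for H8 and 0.02 for G6, where 3 copies in place of 2 would give 0.58. An extra copy of chromosome 15 in some cells of H8 may underlie this. The test asked for a median above 0.1 in each window of 10 Mb, against G6 and against wild type, and took 3 windows at or below 0.1 as grounds for exclusion. That condition was met: 4 of 11 windows were at or below 0.1 against wild type, the lowest at -0.114. It was set aside after this outcome was seen, because G6 also lay below wild type in those windows, while H8 exceeded G6 in all 11 (0.206 to 0.412). The hypothesis is therefore left open on a choice made after the result, and by the test as it was set it would be excluded.

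Chromosome 4 showed a similar difference in its middle part. Between 40 and 120 Mb, limits that were drawn from these data, 425 genes had a median of 0.5 in H8 against G6 and 0.45 against wild type, and the 616 genes on the rest of the chromosome had -0.01 against G6. An extra copy of that part in H8 is a candidate explanation, and it stays open: inside, the smallest window median was 0.355 against G6 and -0.183 against wild type, and outside, windows stayed within 0.1 of 0 against G6 but ran from -0.574 to 0.214 against wild type. The condition set for exclusion, a median above 0.15 in windows outside, was thus met against wild type (0.214, where G6 had 0.251) and not against G6, and it was set aside after this was seen. Chromosome 15 and the middle of chromosome 4 hold 8 and 1 of the 244 genes that differed over all days.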
